A study of Mus musculus with 6 samples.

How the data were processed

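Gene expression was measured on 6 Agilent mouse arrays, 1 array per sample. The samples were lysozyme-expressing dendritic cells of mouse Peyer's patches that carried the C5a receptor (C5aR+ LysoDCs), of which 3 were unstimulated and 3 had been given 100 nM recombinant C5a for 3 h, per the labels. The culture time of the unstimulated samples is not given in the sources used here. Per the labels' protocols, CD11c-positive cells were enriched with beads, the cells were sorted and cultured with CSF-1 and CSF-2, and labelled cRNA (Cy3, 1 colour) was made from total RNA. Nothing in the labels says whether the replicates came from separate animals or cell preparations, so p values measure the spread between these samples, which may in part be technical.

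Per the file headers, the arrays (design 074809) were scanned and read with Agilent Feature Extraction 10.10.1.1 under protocol GE1_1100_Jul11. The deposited scanner files give the intensity of each spot, as a processed signal with background subtracted within the array and, separately, the median brightness of the spot and of its local background. They also hold flags, set to 0 or 1 per spot, for spots well above background, saturated spots and spots that Feature Extraction marked as non-uniform or out of line with their replicate spots. No scaling between arrays had been applied to these values, per the file headers. The deposited series table holds log2 values. Set against the scanner files, 98.9% of the differences between its columns lay within 0.01 of the differences in log2 processed signal less each array's 75th percentile over all probes. Its scale and direction are therefore known, while the baseline subtracted from each probe is not. Its column medians were 0.17, -0.08 and 0.18 for untreated 1 to 3 and 0.01, -0.02 and 0.22 for C5a 1 to 3. It served as an alternative.

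Each array held 62976 spots, of which 59305 were not controls and represented 56605 probes. Control spots were left out, and spots of 1 probe were averaged as log2 processed signal. Spots with an outlier mark (112 to 138 per array) were left out of this average unless all spots of the probe had one. No spot was saturated. A probe counted as well above background on an array where at least 0.5 of its spots were. By this measure 48672 probes were well above background on 0 arrays, 4958 on at least 3 and 2370 on all 6. Per array, 2727 to 6959 probes were, which limits what the arrays can show to the brighter transcripts. The number of arrays limits the precision of each value.

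The scanner files give accessions and no gene names. RefSeq accessions, compared without their versions, were named through a table of assembly GRCm38.p6, which matched 32994 of the 56605 probes and 3746 of the 4958 kept probes. Other probes keep the array's own identifier. The array design cites build mm9, which differs from the table's assembly, so no coordinates are given.

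Values were scaled by subtracting each array's 75th percentile of log2 processed signal over the 2370 probes well above background on all 6 arrays. The plan written before the data were examined took this percentile over all probes. Since under 1 probe in 5 was detected, that percentile lies within the background, and the percentile over detected probes was used for this reason, decided from the detection counts before any comparison was computed. The scaling as first planned is given as an alternative. Probes well above background on at least 3 of the 6 arrays, whatever their group, were kept. For each gene the kept probe with the highest mean over all arrays was taken, which left 4488 genes, 3276 of them with a symbol and 1212 known by probe only. Among the 114 named genes that were tested, 11 had more than 1 kept probe, and in 2 of these (Hspa5 and Tnfaip2) another probe had the opposite sign. A probe not well above background on any array of a group has only a bound there, which concerns detection and not the spread between samples. Its fold is given as "at least", from the brighter group's mean against the mean, per array of the dimmer group, of the higher of that probe's signal and the lowest signal of any probe well above background.

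The groups were compared with limma 3.58.1 (lmFit and eBayes, in R 4.3.3), as C5a minus untreated, with Benjamini-Hochberg adjustment over all 4488 genes and a threshold of 0.05. Gene lists were tested with limma's camera at its preset correlation of 0.01, again with a correlation estimated from the data, and with fry. The 28 response lists were adjusted together, and the cell type lists as a family of their own where at least 3 members were measured. The response lists include complement receptors and components, immediate early genes, MAP kinase feedback genes, NF-kB pathway genes, cytokines, chemokines, chemoattractant receptors, interferon-stimulated genes, MHC class II and antigen presentation, costimulation and dendritic cell maturation, integrins and cell adhesion, tight and adherens junctions, phagocytic and pattern recognition receptors, lysosome, proteases and matrix remodelling, lipid mediator synthesis, glycolysis and hypoxia response, oxidative phosphorylation, cholesterol synthesis and uptake, cholesterol efflux and liver X receptor targets, cell cycle, heat shock and unfolded protein response, oxidative stress response, apoptosis and p53 targets, cAMP and G protein signalling genes, support of IgA class switching, and ribosomal proteins. The 13 cell type lists cover lysozyme-expressing phagocytes, conventional dendritic cells of types 1 and 2, plasmacytoid dendritic cells, B cells, plasma cells, T and NK cells, neutrophils, monocytes, mast cells with basophils and eosinophils, epithelium and M cells, stromal and endothelial cells, and red blood cells.

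The lists, the tests, the alternatives (apart from those named in the closing section as added later) and the rule for naming genes were fixed before the data were examined. By that rule the text names up to 10 genes per direction that passed and did not overlap between groups or, where none passed, the 5 with the smallest unadjusted p. It adds C5ar1 and C5ar2, the 3 members of each response list with the smallest unadjusted p, the 2 highest members of each cell type list, and 12 response genes chosen in advance. The text leaves out 1 of the 28 response lists and a few genes that this rule names, while the counts include them. Predicted and unnamed transcripts were left out of the part that ranks genes by p.

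Replicate numbers are shared between the groups in the labels. Whether they pair the samples was checked on each sample's deviations from its group mean over the 4488 genes. Same-numbered samples correlated at 0.211, 0.269 and 0.384 for numbers 1, 2 and 3, and samples of different numbers at 0.0712 or less, with genes not being independent replicates. The labels do not say that the numbers pair the samples, and a chance matching stays open. Deviations within a group cancel out, so high same-number correlations lower the others, and the contrast is not independent evidence. The fit with the replicate number as a block was therefore run beside the fit without it.

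The gene test was tested on simulated data with the spread of these arrays, 200 changed genes among 4488 and 20 simulations per fold. It recovered 0% of the genes changed by 2-fold, 59.5% of those changed by 4-fold and 89.2% of those changed by 8-fold, with 0.05, 6.55 and 9.3 false calls on average. For the gene lists, camera gave an unadjusted p under 0.05 in 100% of 200 simulated lists of 10 genes shifted by 1 on the log2 scale, and in 4.5% of lists that were not shifted. The simulated genes varied independently, with no effect of replicate number, so these rates hold for uncorrelated genes alone. Camera with an estimated correlation was not simulated, so how often it finds a real shift is not known. In the data the estimated correlation of the response lists ran from -0.27 (lipid mediator synthesis) to 0.66 (cell cycle), with 0.35 for cytokines.

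The alternatives were normexp background correction (offset 50, on the median signals, which are those the scanner files give, where the plan had named mean signals), other scalings, other filters on dim probes, other rules for several probes of a gene, the series table, the replicate block, the row of the slide, other variance and weight settings, other thresholds and leaving out each sample. All 6 arrays lay on 1 slide. Row 1 of the slide held the 3 untreated arrays and C5a 1, and row 2 held C5a 2 and C5a 3.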

Results

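The series addresses whether C5a, the small fragment released when complement component C5 is cleaved, triggers intracellular signalling in C5aR+ LysoDCs. LysoDCs are lysozyme-expressing mononuclear phagocytes of the Peyer's patch, the lymphoid tissue of the small intestine. Sorted cells were left unstimulated (3 samples) or received 100 nM C5a for 3 h (3 samples), and their RNA was hybridised to 1-colour arrays. Values below are log2 signals relative to each array's 75th percentile over detected probes, differences are C5a minus untreated, and n = 3 per group. Unless stated, SEs, intervals and p values of the C5a comparison come from the fit without the replicate block.

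The arrays were dim and uneven. Of 56605 probes, 3574, 6959 and 2727 were well above background on untreated 1, 2 and 3, and 4864, 6651 and 3668 on C5a 1, 2 and 3. Before scaling, the 75th percentile of processed signal over probes detected on all arrays ran from 109 on untreated 3 to 460 on untreated 2, a 4.23-fold range. Over the 4488 genes tested, arrays correlated with each other at 0.844 to 0.960.

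**Figure D1:**
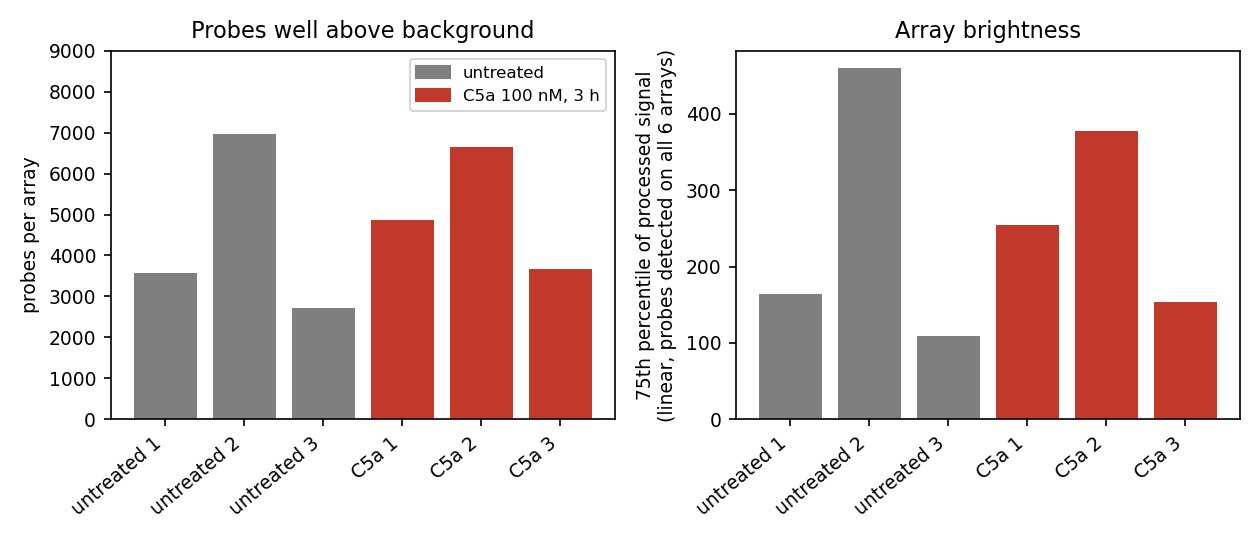
Left, number of probes well above background on each of the 6 arrays; right, the 75th percentile of processed signal on a linear scale, over the probes detected on all 6 arrays, with untreated samples in grey and C5a samples in red. Untreated 2 (460) and C5a 2 (377) were the brightest arrays and untreated 3 (109) the dimmest.

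No gene passed the test between C5a and untreated cells. In limma with Benjamini-Hochberg adjustment, 0 of 4488 genes had an adjusted p under 0.05, and the lowest adjusted p was 0.9992. At an unadjusted p under 0.05 there were 105 genes, 71 higher and 34 lower with C5a, where chance alone gives 224. The 3 samples of a group lay on 1 side of the 3 of the other for 255 genes (5.68%), 151 higher and 104 lower with C5a, and chance gives 10%. These chance values hold for unpaired samples, as does the one for the listed genes. The median gene's difference had an SE of 0.37, so that its 95% interval reached 0.87 to either side (1.83-fold). When all probes were tested without a filter on dim signals, limma with Benjamini-Hochberg adjustment called 47 genes, 9 higher and 38 lower, of which 42 were well above background on at most 1 array.

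The 5 genes with the smallest unadjusted p in each direction did not pass. Those with a positive difference were Rpl14 (probe A_55_P2070913), Erh, Tuba1a, Actn4 and Ier5. Rpl14, a protein of the large ribosomal subunit, was at 0.51 ± 0.30 (SD) with C5a against -1.63 ± 0.78 in untreated cells, a log2 difference of 2.13 (SE 0.43, unadjusted p = 0.00158). Erh differed by 1.27 (SE 0.32) and Actn4, an actin-crosslinking alpha-actinin, by 0.99 (SE 0.26), with untreated signal well above background on 2 and 1 of the 3 arrays. Tuba1a, an alpha-tubulin, was well above background on all 3 C5a arrays and on 0 of 3 untreated arrays, and its signal was at least 3.38-fold higher with C5a. Ier5, an immediate early response gene, differed by 1.76 (SE 0.48), with values of -2.62, -1.25 and -2.93 in untreated 1 to 3 and -0.68, -0.78 and -0.06 in C5a 1 to 3.

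Those with a negative difference were Rpl13a (probe A_55_P2058953), Grina, Pigt, Chtf8 and Slc4a2. Rpl13a, also of the large ribosomal subunit, was at -2.80 ± 0.97 with C5a against -0.37 ± 0.08 in untreated cells, a difference of -2.42 (SE 0.48, unadjusted p = 0.00143). Slc4a2, an anion exchanger, differed by -2.37 (SE 0.72), and Pigt, part of the enzyme that attaches GPI anchors, by -2.20 (SE 0.59). Slc4a2 was well above background on 3 untreated and 2 C5a arrays, Pigt on 2 and 1, and Grina on 2 and 2. Grina and Chtf8 differed by -1.12 (SE 0.29) and -0.95 (SE 0.28). For each of the 10 genes, the groups did not overlap and the sign of the difference was the same under each alternative in which the gene was measured. The genes were picked for a small p on these same arrays, so neither trait is separate evidence of a difference. Foxp4, a forkhead transcription factor, was chosen after its values were seen. It was the other gene well above background on all 3 C5a arrays and on 0 untreated arrays. By the same bound, which leaves out the spread between samples, it was at least 1.19-fold higher. Probes of Ncf1 and Htra2 had the same detection pattern, but another probe of each gene was well above background in untreated cells. No probe had the opposite pattern. The real split thus had 4 probes well above background on 1 side only, where other splits of the 6 samples into groups of 3 had 2 to 812. The other splits that also set all same-numbered samples apart had 2 to 5.

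The receptor for C5a gave a weak signal. C5ar1 (probe A_55_P2830823) was well above background on 1 of 3 untreated and 2 of 3 C5a arrays. Its level was -3.62 ± 0.36 (SD) in untreated and -3.89 ± 0.97 in C5a samples, a difference of -0.28 (SE 0.51, 95% interval -1.47 to 0.92), and the sign turned in 8 of 21 alternatives. C5ar2, the other C5a receptor gene, was well above background on no array and was not tested.

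The genes in the lists fixed in advance did not pass either. Of 358 measured genes in the 28 response lists, 0 were called over all genes tested by limma with Benjamini-Hochberg adjustment, and 0 when adjusted over the lists alone (lowest adjusted p 0.9988). At an unadjusted p under 0.05 there were 8, where chance gives 17.9. Among these were Ier5, Hmox1, Hk2 and Zfp36 with a positive difference and Ptafr, Rtp4 and Npc1 with a negative one. Of the 114 named genes with a value, 43 changed sign when 1 of the samples was left out. Within single lists the count adjusted over the list alone was 0 in all of them, with a lowest adjusted p of 0.0801 among immediate early genes. In the set test, limma's camera with Benjamini-Hochberg adjustment over the lists, 0 of 28 passed, and 2 had an unadjusted p under 0.05. With an estimated correlation the lowest adjusted p was 0.975, and 0 lists passed fry (lowest adjusted p 0.927).

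**Figure D2:**
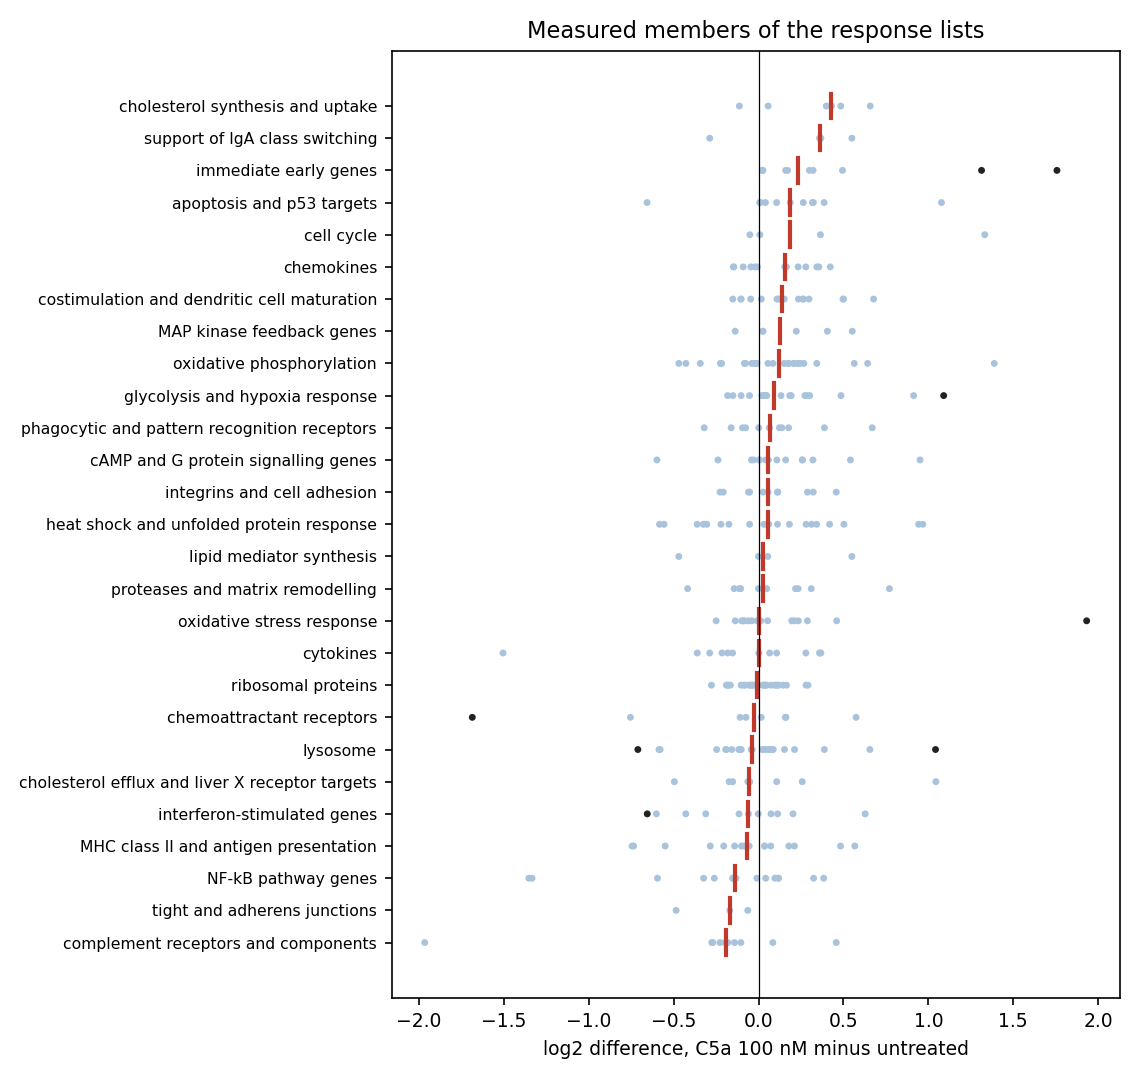
Each point is a measured gene of a response list, placed by its log2 difference between C5a 100 nM and untreated samples; dark points had an unadjusted limma p under 0.05 (8 genes), and the red bar is the list's median. The medians ran from -0.19 for complement receptors and components to 0.43 for cholesterol synthesis and uptake, and no list passed the set test.

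Immediate early genes, which respond within minutes to hours to receptor signals, had the lowest p of the set test. All 10 measured members had a positive difference (median 0.23, camera unadjusted p = 0.0092, adjusted p = 0.258, adjusted p = 0.975 with an estimated correlation). Beside Ier5, Zfp36, which encodes an mRNA-destabilising protein, differed by 1.31 (SE 0.51) and was well above background on 1 untreated and 2 C5a arrays. Jun, a subunit of the AP-1 transcription factor, differed by 0.32 (SE 0.27). Fos was not well above background on any array, and Egr1 was on untreated 2 alone, so neither was tested. The list passed with normexp background correction (camera adjusted p = 0.0106). It also passed without C5a replicate 1 (camera adjusted p = 0.00501) and without the filter (camera adjusted p = 0.00098). With an estimated correlation the adjusted p in these settings was 0.996, 0.94 and 0.289. With normexp 5 of 10 members had a positive difference. Without the filter 13 members had a positive and 13 a negative difference. Their median there was -0.01, where that of all genes was -0.41. The 6 measured MAP kinase feedback genes (camera adjusted p = 0.74) included Dusp16, Dusp1 and Dusp2, phosphatases that dampen MAP kinases, at 0.41 (SE 0.33), 0.22 (SE 0.26) and 0.55 (SE 0.88).

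Of 16 measured NF-kB pathway genes, 10 had a negative difference (median -0.14, camera adjusted p = 0.701). Tnfaip3, an NF-kB inhibitor, differed by -1.35 (SE 0.68) and Traf1 by -0.26 (SE 0.25). The value for Cflar, -1.33 (SE 1.30), rested on C5a 1, at -6.40 where the other 5 samples lay between -2.66 and -1.01. Nfkbia, which encodes the inhibitor IkB-alpha, was well above background on all 6 arrays and differed by -0.15 (SE 0.45). Among 13 measured cytokine genes, 7 differences were positive and 6 negative (camera adjusted p = 0.859). Il1b differed by -0.22 (SE 0.41), Il6 by -0.29 (SE 1.00), Tnf by -0.15 (SE 1.12) and Il10 by 0.36 (SE 1.00). With the replicate block their SEs were smaller, at 0.22, 0.20, 0.30 and 0.40 in this order, and none of them passed. Another kept probe of Il1b, Il6 and Tnf differed by -0.255, -0.285 and -0.749. The largest differences of this list by p were Ebi3 at -1.51 (SE 1.14), Hbegf at 0.36 (SE 0.30) and Il1rn at 0.28 (SE 0.37). With the slide row as a covariate, which sets C5a 1 alone against the 3 untreated arrays of row 1, both lists passed on the lower side (camera adjusted p = 3.88e-05 for NF-kB pathway genes and 0.00412 for cytokines, adjusted p = 0.767 with an estimated correlation for both). Both also passed without C5a replicate 3 (camera adjusted p = 0.00355 and 0.0426, adjusted p = 0.885 with an estimated correlation for both). That fit leaves number 3 in the untreated group alone, and the slide row fit has number 1 alone on the C5a side. Both lists were higher in number 3 than in number 1, by a median of 1.69 for cytokines. Neither fit therefore parts C5a from the replicate number.

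**Figure D3:**
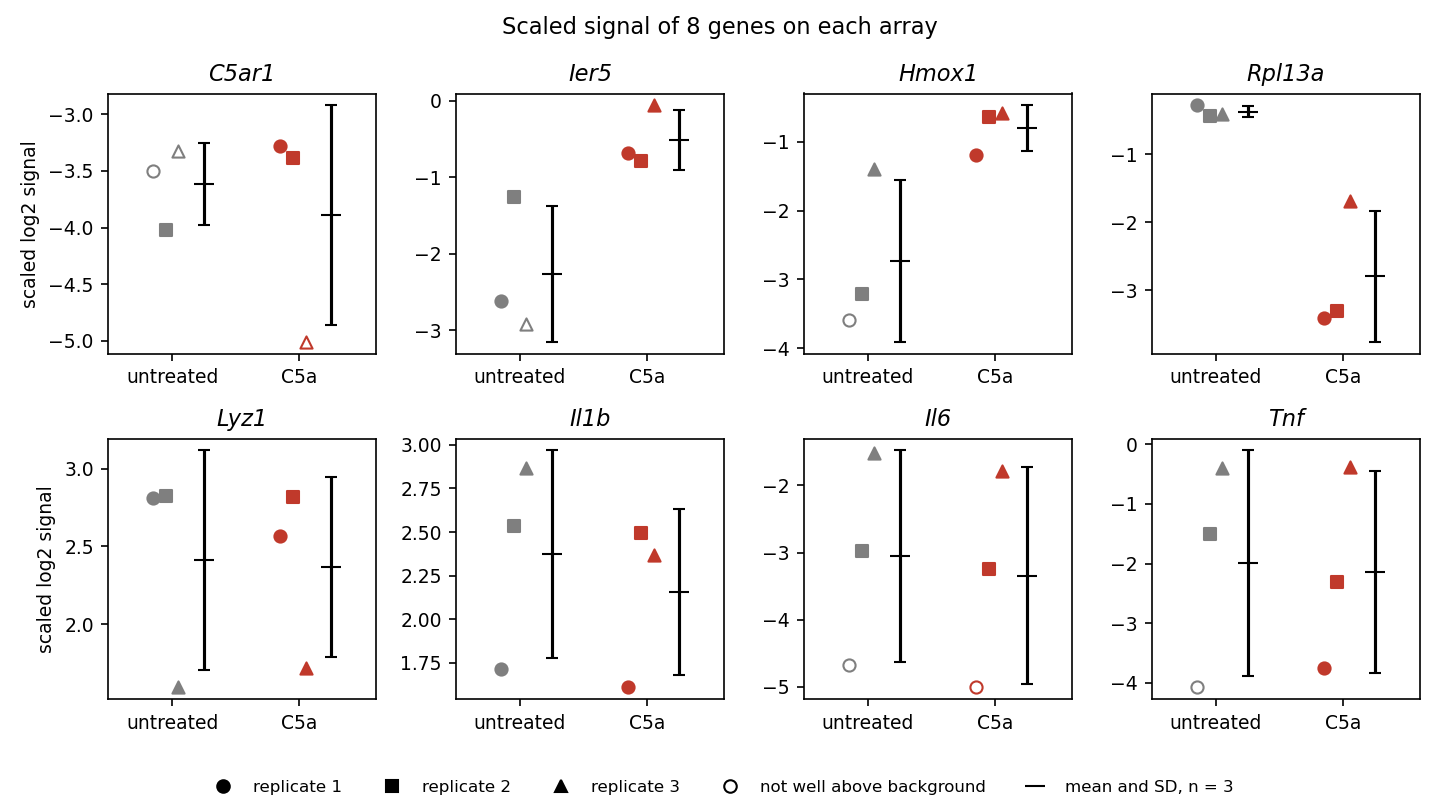
Scaled log2 signal of 8 genes on each array, untreated in grey and C5a 100 nM in red, with the replicate number as the symbol and open symbols for arrays on which the probe was not well above background; horizontal ticks with bars are the mean and SD of 3 samples. Ier5 and Hmox1 were higher and Rpl13a lower in all 3 C5a samples, without passing the adjusted test, while Il6 and Tnf differed more between replicate numbers than between groups.

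Of the chemokine list, 10 members were well above background on all 6 arrays, and none of the 13 measured passed (median 0.15, camera adjusted p = 0.859). Ccl3 was at 0.52 ± 1.57 (SD) in untreated and 0.94 ± 0.99 in C5a samples. Cxcl10 differed by 0.36 (SE 0.28), Ccl24 by 0.28 (SE 0.55), Cxcl1 by 0.34 (SE 1.22) and Cxcl2 by 0.16 (SE 0.71), while Ccl2 was well above background on no array. Of 8 measured chemoattractant receptors (camera adjusted p = 0.701), Ptafr, the receptor for platelet-activating factor, differed by -1.69 (SE 0.57, unadjusted p = 0.0215), with C5a signal well above background on 1 of 3 arrays. Ccr9 differed by -0.75 (SE 0.88) and Ltb4r1, a leukotriene B4 receptor, by 0.57 (SE 0.72), and their signs turned without C5a 3 and without C5a 1. Among 11 interferon-stimulated genes (camera adjusted p = 0.701), Rtp4 differed by -0.66 (SE 0.27), Gbp3 by 0.63 (SE 0.35) and Oasl1 by -0.60 (SE 0.40).

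Antigen presentation and maturation genes gave no call. Of 16 measured members of the MHC class II and antigen presentation list (camera adjusted p = 0.701), H2-Eb1 differed by -0.75 (SE 0.44), H2-Aa by -0.74 (SE 0.50) and Psmb9, an immunoproteasome subunit, by 0.57 (SE 0.42). In the costimulation and maturation list, 12 of 16 differences were positive (median 0.14, camera adjusted p = 0.701), with Socs1 at 0.68 (SE 0.66), Cd274, which encodes PD-L1, at 0.26 (SE 0.32) and Cd200 at 0.50 (SE 0.61). The 4 measured genes that support IgA class switching (camera adjusted p = 0.859) included Tgfb1 at 0.37 (SE 0.56) and Il10. Of 12 phagocytic and pattern recognition receptors (camera adjusted p = 0.882), Tlr2 differed by 0.67 (SE 0.54), Tlr9 by -0.32 (SE 0.43) and the scavenger receptor Cd36 by 0.39 (SE 0.53). Among 10 complement receptors and components, 8 differences were negative (median -0.19, camera adjusted p = 0.701). C1qa differed by -0.27 (SE 0.49) and Itgax, the CD11c chain, by 0.46 (SE 0.37). Cfp, which encodes properdin, had a difference of -1.97 (SE 1.58) that rested on C5a 3, at -4.66 where the other 5 samples lay between 0.37 and 2.16, and its other kept probe differed by less.

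Genes of adhesion and digestion showed no shift past the test. Integrins and adhesion genes (11 measured, camera adjusted p = 0.859) included Itgav at 0.32 (SE 0.38) and Cd47 at -0.21 (SE 0.33). Only 3 junction genes were measured, Ctnnb1, F11r and Ctnna1, at -0.49 (SE 0.42), -0.17 (SE 0.31) and -0.06 (SE 0.38), with a camera adjusted p of 0.701. Of 24 lysosomal genes (camera adjusted p = 0.74), Npc1, a lysosomal cholesterol transporter, differed by -0.71 (SE 0.30, unadjusted p = 0.0489) and Atp6v0d1 by -0.59 (SE 0.27). Among 10 proteases and matrix genes (camera adjusted p = 0.956), Spp1 differed by 0.77 (SE 0.55), F10 by -0.42 (SE 0.54) and Plaur by 0.22 (SE 0.31). With the replicate block the SE of Spp1 was 0.21 (limma unadjusted p = 0.0147, adjusted p = 0.926). The 4 lipid mediator genes (camera adjusted p = 0.78) included Tbxas1, thromboxane synthase, at -0.47 (SE 0.27), Ptges at 0.05 (SE 0.28) and Ptgs2, which encodes cyclooxygenase-2, at 0.55 (SE 0.98).

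Metabolic lists likewise gave no call. Cholesterol synthesis and uptake genes had the other unadjusted p under 0.05, with 6 of 7 differences positive (median 0.43, camera unadjusted p = 0.0322, adjusted p = 0.451, adjusted p = 0.975 with an estimated correlation). Its members included Hmgcs1 at 0.43 (SE 0.27) and Idi1 at 0.66 (SE 0.50). The 8 cholesterol efflux and liver X receptor genes (camera adjusted p = 0.859) included Nr1h3 at 1.04 (SE 0.55), Srebf1 at -0.50 (SE 0.41) and Nr1h2 at -0.15 (SE 0.24). In the glycolysis and hypoxia list, 14 of 18 differences were positive (median 0.09, camera adjusted p = 0.701), among them Hk2, a hexokinase, at 1.09 (SE 0.36, unadjusted p = 0.0185), Hif1a at 0.49 (SE 0.31) and the glucose transporter gene Slc2a1 at 0.91 (SE 0.60). Of 26 oxidative phosphorylation genes (camera adjusted p = 0.836), Cox6c differed by 1.39 (SE 0.89), Sdha by 0.64 (SE 0.42) and Ndufs1 by -0.43 (SE 0.33). Hk2, Slc2a1, Idi1, Nr1h3 and Sdha were well above background on only 1 untreated array. The signs of Idi1, Nr1h3 and Sdha turned with normexp.

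Stress and growth genes were similar. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, was at -0.80 ± 0.34 (SD) with C5a against -2.74 ± 1.18 in untreated cells, a difference of 1.93 (SE 0.58, unadjusted p = 0.0122), and was well above background on 3 and 2 arrays of these groups. Of the other oxidative stress genes, Nfe2l2 differed by 0.46 (SE 0.48) and Ftl1 by 0.21 (SE 0.24), and the list of 16 had 8 differences in each direction (camera adjusted p = 0.74). The 20 heat shock and unfolded protein response genes (camera adjusted p = 0.859) included Hspa5 at 0.94 (SE 0.47), whose other probes had the opposite sign, Hsp90ab1 at 0.50 (SE 0.33) and Hspe1 at 0.34 (SE 0.27). In the apoptosis and p53 list, 10 of 11 differences were positive (median 0.19, camera adjusted p = 0.701), with Bak1 at 1.08 (SE 0.67), Casp1 at -0.66 (SE 0.52) and Mdm2 at 0.32 (SE 0.35). Of 15 cAMP and G protein genes, 11 differences were positive (camera adjusted p = 0.701), with Rgs2 at 0.95 (SE 0.48), Gna13 at 0.54 (SE 0.31) and Gnai3 at -0.60 (SE 0.61), whose sign turned without C5a 3. Cell cycle genes were mostly dim, with 22 members well above background on no array. The 4 measured (camera adjusted p = 0.701) included Mcm4 at 1.33 (SE 0.65), Pcna at 0.36 (SE 0.48) and Mki67 at -0.05 (SE 0.54). Bak1 and Mcm4 were well above background on only 1 untreated array, and their signs turned with normexp. Ribosomal protein genes of the fixed list spread little, from -0.28 for Rpl5 to 0.29 for Rps18 over 29 measured members (camera adjusted p = 0.836), with Rpl30 at 0.28 (SE 0.28) and Rpl11 at -0.18 (SE 0.25). For 5 lists the median, the mean and the set test did not all point the same way, and the set test pointed to the lower side in each. Their medians and means were 0.00 and -0.09 for cytokines, 0.03 and 0.03 for lipid mediator synthesis, -0.06 and 0.06 for cholesterol efflux, -0.01 and 0.00 for ribosomal proteins, and -0.04 and 0.04 for lysozyme-expressing phagocytes.

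Markers of the sorted cells were detected in both groups. Of the lysozyme-expressing phagocyte list, Lyz1, Lyz2, Itgax, Itgam, Sirpa, H2-Ab1 and Csf1r were well above background on all 6 arrays, while Ccr2, Cx3cr1, Mertk, Cd4, Timd4 and Fcgr1 were on none. Lyz1, which encodes lysozyme, was at 2.41 ± 0.71 (SD) in untreated and 2.37 ± 0.58 in C5a samples, and H2-Ab1 differed by -0.10 (SE 0.29). The other kept probes of H2-Ab1 differed by -0.224, -0.395 and -0.47. The set test over the 9 measured members of the list gave a camera adjusted p of 0.927. Plasmacytoid dendritic cell markers (5 measured, camera adjusted p = 0.787) included Bst2 at 0.50 (SE 0.61) and Siglech at -0.96 (SE 1.40). The value for Siglech rested on C5a 1, at -6.01 where the other 5 samples lay between -2.50 and -0.44. The 3 measured plasma cell markers (camera adjusted p = 0.787) included Xbp1 at 0.11 (SE 0.48) and Prdm1 at 0.10 (SE 0.46).

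The remaining 10 cell type lists had under 3 measured members and no set test. Of 14 B cell markers, 12 were well above background on no array, and Cd79b differed by -0.46 (SE 0.72). For T and NK cells 13 markers were on no array and Il7r, on all 6, differed by -0.22 (SE 0.49). Among neutrophil markers, 10 of the 11 on the array were not detected, and Csf3r differed by 0.22 (SE 0.35). Conventional dendritic cells of type 1 were represented by Irf8 at 0.33 (SE 0.52), those of type 2 by Mgl2 at 0.13 (SE 0.52) and Irf4 at 0.65 (SE 0.58), and monocytes by Plac8 at 0.41 (SE 0.90). In the epithelium and M cell list, 15 markers, Epcam among them, were on no array, and Anxa5 and Tnfaip2 differed by -0.26 (SE 0.29) and -0.13 (SE 0.55). Of the stromal and endothelial list, 14 markers were on no array, and Acta2, a smooth muscle actin, was on all 6 and differed by -0.62 (SE 0.34). No mast cell, basophil and eosinophil marker and no red blood cell marker was measured on enough arrays to be tested.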

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

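The tests in this part were chosen only after the results they concern had been seen.

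On C5a 1, 9 adjacent spots in rows 1 to 8 and columns 135 to 136 of the array stood out among the spots of probes that were not tested, with a processed signal over 50000, against 0 of the same spots on the untreated arrays. The threshold was chosen after the values were seen. Picked in the same way, as spots over it on 1 array and on no other, untreated 1, 2 and 3 had 0, 0 and 1. By another measure, probes well above background on 1 or 2 arrays and over 32-fold brighter on 1 array than on each other array, untreated 3 had 39 and C5a 1 had 10. The 9 spots had a median processed signal of 360395, where the same spots had a median of 5.20 on the untreated arrays and at most 9.46 on the other 5 arrays. Of the 9 spots, 2 were control spots, and the 7 probes included Bcl2l11, Tmem42, Hs3st2, Col28a1 and Notum. Feature Extraction had put an outlier mark on 4 of the 9 spots.

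Without a filter 47 genes were called. They passed only when probes near background were tested, and 3 explanations were set against them. C5a treatment as the cause would need signal on all 3 arrays of a group, which 1 of the 47 had, and the tables argue against it. Light on spots of a single array remains, with 42 well above background on at most 1 array, 37 brightest on untreated 3 and 8 on C5a 1. All 7 probes of the bright patch were among the 9 genes called higher. A spread shared with many background probes may also contribute, since with the same probes and the 75th percentile over all probes, which matches background levels between arrays, 0 genes were called (limma with Benjamini-Hochberg adjustment, 1063 at an unadjusted p under 0.05).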

How the results depend on the processing

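The 75th percentile over all probes was the scaling first planned and became an alternative once the detection counts had been seen. Chosen after seeing the data were array brightness as a covariate, the median over detected probes, and no filter together with the percentile over all probes. Under 26 of 28 alternatives 0 genes were called by limma with Benjamini-Hochberg adjustment, and the exceptions were 47 without a filter on dim probes and 55 at an unadjusted p under 0.05 with a fold of at least 2, which is not adjusted. Without each sample in turn the count was 0, with 91 (without untreated 3) to 214 (without untreated 2) genes at an unadjusted p under 0.05 against 105 with all samples. That count was 25 with centring on the median over all probes, 26 without scaling, 27 with normexp and 37 with the 75th percentile over all probes or the series table. With the replicate block 0 genes were called (lowest adjusted p 0.926, 190 at an unadjusted p under 0.05), 0 lists passed (lowest adjusted p 0.36), and no other call changed. The slide row as a covariate gave 0 genes (lowest adjusted p 0.0615).

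Lists past camera numbered 0 under 18 of 24 alternatives. With normexp background correction 3 passed (immediate early genes, oxidative stress response and ribosomal proteins), without a filter 15, with the slide row as a covariate 2, within row 1 alone 2, and without each sample in turn 0 to 2, which were immediate early genes without C5a replicate 1 and NF-kB pathway genes and cytokines without C5a replicate 3. Of the 25 list calls in any setting, 0 passed with an estimated correlation, a version of the test whose success rate was not simulated. Row 1 has C5a 1 as its only C5a array, so these fits compare that sample with all 3 untreated ones. Leaving out 1 sample leaves its number in 1 group alone, so those fits do not part C5a from the replicate number. For normexp and for no filter the cause was not tested. Without a filter the set test pointed up for all 15 lists, against a median of -0.41 over all genes. Chemokines, among them, had 8 positive and 21 negative differences. Of the listed response genes, 1 was called without a filter, Bcl2l11, whose probe taken there lies in the bright patch of C5a 1, and 0 under the other alternatives.

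Of 2426 values of the named genes other than C5ar1 under the alternatives, 217 moved by more than 1 SD, 229 changed sign and 0 were called. C5ar1 ranged from -0.58 to 0.33. The median difference over all genes was 0.04 and became 0.46 with centring on the median over all probes, 0.40 with the 75th percentile over all probes or the series table, 0.32 without scaling, 0.14 with the slide row, -0.12 with normexp and -0.41 without a filter. Not run were the slide as a block, since all arrays lay on 1 slide, and, for 61 of the 114 named genes, C5ar1 and 7 of the 10 with the smallest p among them, the filter to probes well above background on all 6 arrays, where they have no value. With 48672 of 56605 probes well above background on no array, most dim transcripts, Fos and C5ar2 included, had no measurable level.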

Other observations

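In this part, the tests of matching the numbers by chance and of activation differing between numbers, and the genes named for their differences between replicate numbers, were chosen only after the results had been seen.

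In both the untreated and the C5a samples, replicate 3 had the highest and replicate 1 the lowest level of Il6, Tnf and Cxcl1, which encode secreted mediators of inflammation. These and the genes below were picked for large differences between the numbers, and none passed the test. Tnf was at -4.07, -1.51 and -0.39 in untreated 1, 2 and 3 and at -3.76, -2.30 and -0.37 in C5a 1, 2 and 3. Il6 differed by 3.19 on the log2 scale between numbers 3 and 1, Cxcl1 by 3.84, Tnf by 3.54, Il10 by 3.02 and Ptgs2 by 3.02. The transcription factor gene Irf1 differed by 3.34, the chemokine receptor gene Ccr7 by 2.69, Ccl3 by 2.52 and Rnd1 by 4.03. In the other direction, Ifitm1, Havcr2, S100a6 and Plet1 were lowest in replicate 3 of both groups, by -2.73, -2.56, -2.39 and -2.50 against number 1. Over all 4488 genes, limma with Benjamini-Hochberg adjustment called 0 between the numbers (lowest adjusted p 0.173), with 801 at an unadjusted p under 0.05.

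Of 84 list tests between the numbers, 18 passed camera, in 11 lists, and 0 passed with an estimated correlation. Between numbers 3 and 1, cytokines had a median difference of 1.69 (camera adjusted p = 5.25e-05, adjusted p = 0.773 with an estimated correlation) and NF-kB pathway genes were likewise higher in number 3 (camera adjusted p = 5.25e-05, adjusted p = 0.773 with an estimated correlation). Between numbers 3 and 2, chemokines had a median difference of 1.15 (camera adjusted p = 0.00264, adjusted p = 0.773 with an estimated correlation). Chemokines did not pass between numbers 2 and 1 (camera adjusted p = 0.618). The lists past camera were not particular to inflammation. Between numbers 2 and 1 they included heat shock and unfolded protein response (camera adjusted p = 0.00567, adjusted p = 0.773 with an estimated correlation) and lysosome (camera adjusted p = 0.014, adjusted p = 0.789 with an estimated correlation), both higher in number 2. Cell cycle was higher (camera adjusted p = 0.0123, adjusted p = 0.773 with an estimated correlation) and oxidative phosphorylation lower (camera adjusted p = 0.0309, adjusted p = 0.789 with an estimated correlation) in number 3 than in number 1, and ribosomal proteins were higher in number 3 than in number 2 (camera adjusted p = 0.0241, adjusted p = 0.789 with an estimated correlation). The others were phagocytic and pattern recognition receptors, support of IgA class switching, and costimulation and dendritic cell maturation.

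Same-numbered samples of the 2 groups thus deviated together, at correlations of 0.211 to 0.384 across genes. Array brightness shared by number as the cause stays open. Number 2 was the brightest (460 untreated, 377 C5a) and number 3 the dimmest (109 and 154) in both groups. With quantile normalization over genes well above background on all 6 arrays the lowest same-number correlation was 0.279. This lay above the limit set beforehand for brightness as the cause. But that normalization only matches the distributions of the arrays, and cannot remove a dependence on brightness that differs between genes. A chance matching stays open, because only 1 of the 6 ways to match the samples, the real one, had a mean correlation as high (0.288, against 0.165 for the next), and 6 matchings are too few to exclude it. Activation of the cells that differed between replicate numbers is a hypothesis that may account for the cytokine values. With an estimated correlation, 0 of 9 tests of the cytokine, chemokine and NF-kB lists passed. How often that version finds a real shift was not simulated, so this does not decide the question. The labels do not say what the numbers share.

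No gene was called between C5a and untreated cells, and whether array brightness was hiding a difference stays open. With array brightness as a covariate 0 genes were called (limma with Benjamini-Hochberg adjustment, 113 at an unadjusted p under 0.05). A count under the 224 that chance gives had been set as evidence against this before that fit was run. The fit itself was chosen after the data had been seen. But the chance value ignores any pairing by number, and splits that part the numbers as the real one does fall below it without any covariate. The 6 samples make 10 splits into groups of 3, too few for a share under 0.05. All 10 gave as many called genes as the real one, 0, and the highest of the others was 0. At an unadjusted p under 0.05 the real split gave 105 genes, and the 3 other splits that also part all same-numbered samples gave 61 to 119. The 6 splits that keep some numbers together gave 103 to 476, the highest being the split of the 3 dimmer arrays (untreated 1, untreated 3 and C5a 3) from the 3 brighter ones. A split not by brightness (untreated 1, untreated 2 and C5a 1 against the rest) gave 437, and these splits do not part brightness from the replicate numbers. An effect of C5a below the size these arrays can show remains untested.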
